A study of Danio rerio with 58 samples.

How the data were processed

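RNA sequencing libraries of whole wild-type zebrafish larvae (Danio rerio) were used. Per the labels' protocols, embryos were placed in stream water from 6 hours after fertilization, 20 embryos to a dish in 30 mL at 27 °C under 14 hours of light and 10 of dark, and 5 dishes were planned per site. The water came from a stream whose flow is mostly treated wastewater, taken 100 m above a treatment plant's outfall (upstream), at the outfall (effluent) and 100 m below it (downstream), in January and in May. Larvae were collected after 3 or 6 days. The 58 libraries fell into 12 groups of month, age and site, with 5 libraries each except 4 in January 3 d upstream and 4 in May 6 d upstream. A library was taken as a dish. Dishes of a group held water of the same site and month, so p-values measure the spread between dishes and not between water samples. The labels name no sequencing batch, and month cannot be separated from exposure run.

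Each library had a deposited table of 57775 Ensembl transcripts with estimated counts, TPM, transcript length and effective length. Per the submitters' processing notes, FastQC 0.11.5, cutadapt 1.18 and kallisto 0.45.0 were used with build GRCz11; the file headers have kallisto's column names. The deposited estimated counts are reads assigned to transcripts, shared among similar transcripts in fractions, and are not normalized. The deposited TPM values are scaled to transcript length and library total, and were not used in a test. The deposited effective lengths (another unit, in bases) gave a mean fragment length for each library. Counts of transcripts that share sequence with others of the same gene, or with a near-identical gene, are uncertain because the split is an estimate.

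The files do not pair transcripts with genes. Of the 57775 identifiers 0 matched the symbol table and 0 the RefSeq table used here, which hold gene identifiers. All tests were therefore made on transcripts, which the fixed design had allowed for. The lists of named genes fixed beforehand, and the part of the design that would have named genes by symbol, were not analysed here. At most 2 transcripts that rose and 2 that fell are given by identifier. They were chosen among transcripts called in the same direction in all 8 comparisons with upstream, had a mean log2 CPM of at least 1 and had the largest values of their smallest absolute log2 fold change over those comparisons; this choice of set was made after the data were examined.

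Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, the package's default filter on low counts with a minimum of 10 reads, Benjamini-Hochberg adjusted p under 0.05). The 29 libraries of an age were fitted together with a mean per group and a spread shared by the groups of both months. The contrasts were effluent or downstream against upstream, downstream against effluent, and the May minus January difference of each comparison with upstream. A comparison of 6 d with 3 d larvae, on the 9 upstream libraries of a month, was added. A transcript is called where its adjusted p passed. Standard errors of log2 fold changes come from the F statistic.

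The stage index of a library was the mean log2 CPM (prior count 2) of the 200 transcripts that were most higher at 6 d than at 3 d, less that of the 200 most lower, among transcripts called with a mean log2 CPM of at least 1. The transcripts came from upstream larvae of the other month, so no library was in both the index and its test. Groups were compared by two-sided exact permutation tests, adjusted over the 8 comparisons. Values of the index in January and May come from different transcripts and cannot be set side by side. Detected transcripts were counted at 10 or more reads after every library was thinned to 20000000 reads by random draw, and compared in the same way. Overlaps of calls were set beside the number that independent lists give, and for comparisons with the same upstream libraries also beside simulated unchanged groups and beside the values with the upstream libraries split between the comparisons.

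Libraries held 21602411 to 58541705 estimated reads. No replicates were duplicates: the smallest chi-square per degree of freedom between replicates was 10.4. In data simulated from the real means and spreads, 50 transcripts at each of 4 fold sizes were changed. For effluent against upstream, January 3 d, with 38151 transcripts, 22% of 1.5-fold, 74% of 2-fold and 92% of 4-fold changes were called, with 6 false calls among 145. For May 6 d, with 37818 transcripts, the shares were 16%, 50% and 90%, with 8 false calls among 135. The simulation drew each transcript independently, with the same spread in all groups. These shares may not hold where replicates differ together or the spread differs between months.

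The alternatives fixed before the data were examined were median-of-ratios factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, an offset for effective length, a fit of a single month, each library left out in turn, and for the stage index 50 or 500 transcripts per direction. Added after seeing the data were leaving out libraries with a TMM factor below 0.85, thinning, limma 3.58.1 (voom with library quality weights), mean fragment length as a covariate, fits of only the groups compared, and the library's score on the first axis along which replicates of a group differ as a covariate (called the replicate axis).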

Results

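Whole zebrafish larvae raised in water from an effluent-dominated stream were profiled to ask how gene expression differs with the site and season the water came from. The 58 libraries covered water from upstream of the outfall, the effluent itself and downstream of it, in January and May, after 3 and 6 d. Libraries held 21602411 to 58541705 estimated reads, and the 9 May upstream libraries 22581799 to 29023696, a narrow and low range beside the 22036337 to 58541705 of the other May libraries. The labels name no sequencing run, so a separate run of the May upstream libraries cannot be told apart from site in the May comparisons. Because the files pair no transcript with a gene name, results are given for transcripts and for groups of transcripts defined by abundance or by change with age.

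The number of transcripts detected per library at equal depth differed with site, and in opposite directions in the 2 months. The labels give no measure of RNA quality, so a difference in library quality cannot be told apart from a difference in expression. At 20000000 reads per library, January 3 d upstream larvae had 31199 ± 406 transcripts at 10 or more reads (SD, n = 4), against 29209 ± 1049 in effluent and 28984 ± 904 in downstream water (n = 5 each). At 6 d the January numbers were 30817 ± 1343 upstream, 28616 ± 1801 in effluent and 27944 ± 2834 downstream (n = 5 each). In May the order turned. At 3 d upstream larvae had 29521 ± 1854 transcripts, effluent larvae 33222 ± 201 and downstream larvae 33114 ± 424 (n = 5 each), and at 6 d the numbers were 30569 ± 305 (n = 4), 32948 ± 156 and 32965 ± 261 (n = 5 each). All 8 differences from upstream passed an exact permutation test (two-sided, adjusted p = 0.0106 to 0.0159 over 8 comparisons). The January 6 d differences did not pass at a minimum of 50 reads (exact permutation test, adjusted p = 0.227 and 0.278), nor without upstream replicate 1 (-1601 and -2273 transcripts, adjusted p = 0.0556 and 0.0635). Their sizes were -2201 transcripts in effluent and -2873 downstream, and they became -1146 and -1434 at a minimum of 50 reads. Without effluent replicate 5 the effluent difference was -1431, and without downstream replicate 5 the downstream difference was -1640. The latter library had the lowest TMM factor (0.557) and shortest mean fragment (135 bases) of the 29 libraries of 6 d. The January 3 d effluent difference of -1990 transcripts stayed near that size without upstream replicate 2 (-1844) or upstream replicate 3 (-1913) but did not pass (exact permutation test, adjusted p = 0.0536 for each). Over all alternatives the adjusted p ranged from 0.0212 to 0.0536 there, from 0.0106 to 0.227 in January 6 d effluent and from 0.0106 to 0.278 in January 6 d downstream water.

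**Figure D1:**
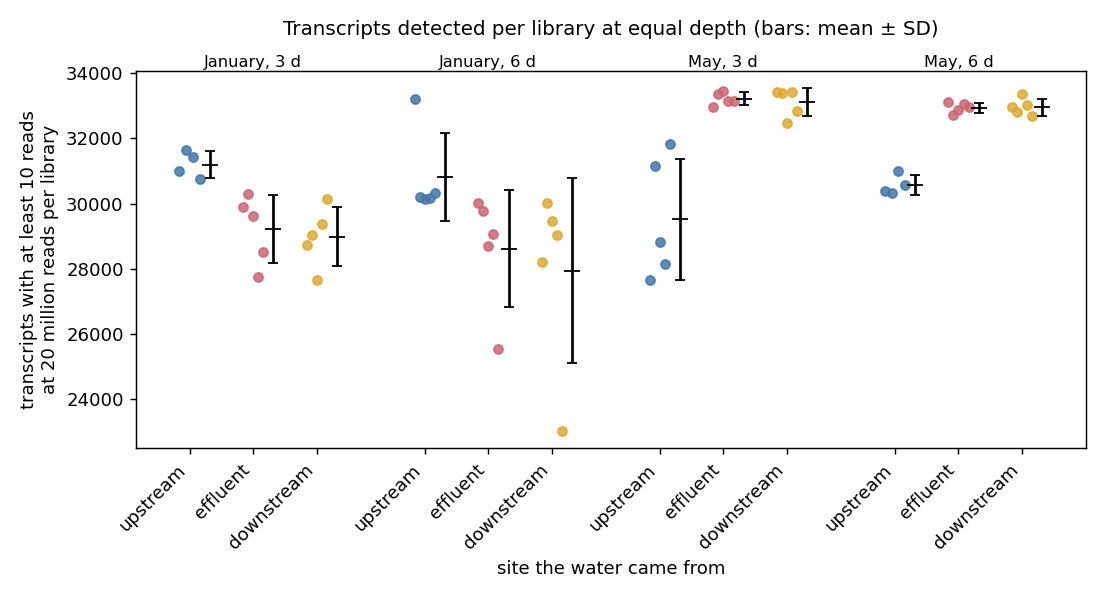
Transcripts with at least 10 reads after thinning each library to 20000000 reads, by site, month and age; points are libraries and bars the mean ± SD. In January effluent and downstream means lie below upstream, and in May they lie above it, in effluent at 33222 against 29521 at 3 d and at 32948 against 30569 at 6 d.

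In January, abundant transcripts were more often called higher than lower in effluent and downstream larvae, while most rare transcripts were not called. At 3 d in effluent, 32.0% of the 2685 transcripts with a mean log2 CPM above 6 were higher and 2.98% lower, while of the 11159 below 0, 2.90% were higher and 6.82% lower. Downstream these shares were 41.3% and 5.33% above 6, and 3.55% and 8.16% below 0. The classes were not tested against each other. Among transcripts called in 3 d effluent, the median log2 fold change was 0.73 for those that rose and -1.33 for those that fell. Their median log2 CPM was 4.12 and 1.57. A rare transcript needs a larger change to be called, so these sizes do not show that falls were larger than rises. In total 8536 of 39208 transcripts (21.8%) were called in effluent, 5228 higher and 3308 lower, and 10615 downstream, 6121 higher and 4494 lower. In a fit of January alone these were 4824 higher and 1758 lower in effluent and 5603 and 2534 downstream, and with limma's quality weights 6835 and 5924, and 7268 and 6918. At 6 d, 10665 of 38802 were called in effluent (5551 higher and 5114 lower) and 11904 downstream (5967 higher and 5937 lower), and 38.0% of the most abundant class was higher in effluent against 5.91% lower. The 3 d count fell to 4907 in effluent and 6746 downstream without upstream replicate 2, and to 5570 in effluent without upstream replicate 3. With the replicate axis as a covariate it was 2230 (1642 higher and 588 lower) and 1489 (1179 and 310), and downstream 6683 (4314 and 2369) with fragment length as a covariate. At 6 d it fell to 6330 and 7666 without upstream replicate 1, to 6901 in effluent without effluent replicate 5, to 3533 (2616 higher and 917 lower) and 4417 (2807 and 1610) in a fit of January alone, and to 5778 and 1526 in fits of the groups compared alone. Under DESeq2 more 6 d transcripts were lower than higher (7487 against 5641 in effluent and 7418 against 6377 downstream). The fit of an age shares its spread over both months, while 6 d libraries of a group differed more in January than in May. Their SD on the first principal component of log2 CPM was 72.7 to 89.6 in January groups and 7.96 to 13.5 in May groups. The January 6 d calls of that fit may thus be too many and the May ones too few.

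In May, abundant transcripts were more often called lower than higher. As with detected transcripts, a difference in library quality cannot be told apart from expression in the abundance classes of either month. At 3 d in effluent, 62.8% of the transcripts above a log2 CPM of 6 were lower and 10.3% higher, while 2574 of the 11159 below 0 were higher and 948 lower. Transcripts that rose had a median log2 CPM of 1.54 and a median log2 fold change of 1.47, and those that fell 3.88 and -0.90. In total 20470 of 39208 transcripts (52.2%) were called in effluent, 10193 higher and 10277 lower. Downstream larvae gave 20035 (9987 higher and 10048 lower). At 6 d the calls were 14001 of 38802 in effluent (7575 higher and 6426 lower) and 13081 downstream (7088 higher and 5993 lower), and 5990 transcripts rose at least 2-fold in effluent against 2093 that fell as much. With the replicate axis as a covariate more transcripts were lower than higher: the 3 d counts were 10839 (4496 higher and 6343 lower) and 10763 (4535 and 6228), and the 6 d counts 14199 (6691 and 7508) and 13766 (6521 and 7245). The 6 d counts rose to 22465 and 21802 in a fit of May alone, to 21866 and 21715 with limma's quality weights, and to 20671 and 20893 in fits of the groups compared alone.

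**Figure D2:**
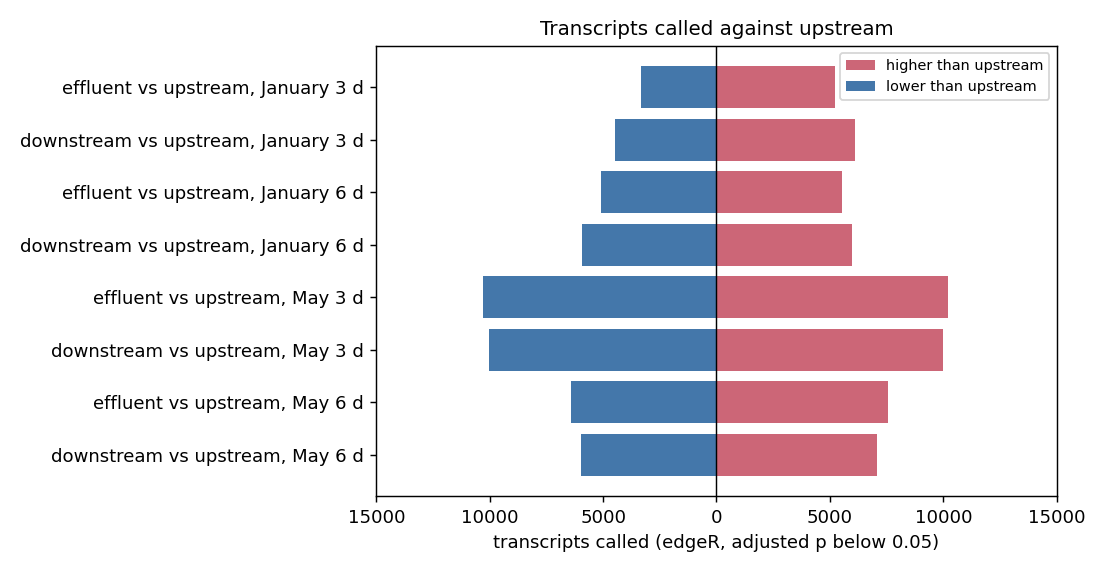
Transcripts called by edgeR (adjusted p below 0.05) as higher (right) or lower (left) than upstream in each of the 8 comparisons. At May 3 d the calls numbered 20470 in effluent and 20035 downstream.

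Larvae in effluent and larvae in downstream water differed little. With all libraries of an age fitted together, edgeR called 0 transcripts between them in either month at either age. Other edgeR fits called 12 in May 6 d (those 2 groups alone), 1 in January 6 d (replicate block), 1 in January 3 d and 2 in January 6 d (replicate axis), and up to 9 with a library left out, in January 6 d without downstream replicate 3. The numbers at an unadjusted p under 0.05 were 1829 (January 3 d), 478 (May 3 d), 1502 (January 6 d) and 770 (May 6 d), where about 1960 at 3 d and 1940 at 6 d would be expected by chance. Numbers far below chance, as in May, may come from p-values that are too large under the shared spread. They do not show that the groups were alike. DESeq2 called 76, 76, 107 and 56, and limma with quality weights 0, 0, 1 and 103. The median absolute log2 fold change between these groups was 0.18, 0.11, 0.17 and 0.13 in the same order, against 0.48 to 0.76 between effluent and upstream. A count of 0 does not show that the groups were the same.

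Effluent and downstream larvae moved largely the same transcripts away from upstream. In May at 3 d 9291 transcripts were higher in both comparisons and 9357 lower in both, where independent lists of these sizes would share 2596 and 2634, and 0 were called in opposite directions. In January at 3 d the shared calls were 4534 higher and 2448 lower against 816 and 379 for independent lists. At 6 d they were 4825 and 3877 in January against 854 and 783, and 6429 and 5244 in May against 1384 and 993. The comparisons use the same upstream libraries. Simulated unchanged groups shared 0 calls, with r across transcripts of 0.50 to 0.59 against an observed 0.86 to 0.93. The covariance of the log2 fold changes exceeded the simulated covariance by 1.99 (January 3 d), 1.87 (January 6 d), 2.51 (May 3 d) and 2.43 (May 6 d). The simulation drew each transcript independently and was fitted for a single month, while real replicates also differ together along the replicate axis. It may therefore understate what the shared upstream libraries add. With the upstream libraries split between the comparisons, and with the parts of that split exchanged, the transcripts called in both fell from 6982 to 2800 and 2043 (January 3 d), from 8702 to 3697 and 2930 (January 6 d), from 18648 to 11907 and 11630 (May 3 d) and from 11673 to 5521 and 5339 (May 6 d). At most 18 of these were called in opposite directions, and r was 0.58 to 0.71. The split leaves each comparison fewer upstream libraries, which can lower the number of calls by itself. The fall in calls therefore does not measure what the shared libraries add. The covariance of the log2 fold changes was 2.34 with shared libraries and 2.036 and 2.007 with the split (January 3 d). In the same order it was 2.124, 1.686 and 1.672 (January 6 d). In May it was 2.789, 2.497 and 2.452 (3 d), and 2.748, 2.562 and 2.535 (6 d). Part of the January overlap rested on single upstream libraries. At 3 d the shared calls fell to 4002 without upstream replicate 2 and 4596 without upstream replicate 3. At 6 d they fell to 5129 without upstream replicate 1. The replicate axis left 1164 (January) and 9551 (May) at 3 d, limma's weights gave 10579 (January 3 d) and 19423 (May 6 d), and fits of a single month gave 2881 (January) and 19898 (May) at 6 d.

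The site differences changed with month for many transcripts. The May minus January difference passed for 19994 of 39208 transcripts in effluent and 20925 downstream at 3 d, and for 19253 and 19001 of 38802 at 6 d. Most transcripts called in both months had moved in opposite directions. In effluent at 6 d 5633 transcripts were called in opposite directions and 162 in the same direction (89 higher and 73 lower), where independent lists would give 1918 opposite. Downstream at 6 d these numbers were 5797 and 181, with 2006 expected opposite. At 3 d 3628 were opposite in effluent and 1222 in the same direction, and 5236 and 1002 downstream. Across transcripts, which are not independent replicates, r between the January and May log2 fold changes was -0.22 in effluent and -0.28 downstream at 3 d, and -0.60 and -0.56 at 6 d. Fisher's exact test over transcripts gave an odds ratio of 0.0928 in effluent at 3 d, as a description only. With the replicate axis as a covariate the May minus January difference was called for 1925 and 2056 transcripts at 3 d, and for 16372 and 16356 at 6 d. At 3 d the direction of the shared calls then turned, with 186 opposite and 638 in the same direction in effluent and 150 opposite and 328 in the same direction downstream. Without that covariate, the opposite calls at 3 d were 2009 and 3305 without January upstream replicate 2, and 2345 in effluent without replicate 3 of that group. At 6 d they were 3309 and 3709 without January upstream replicate 1 and, without January effluent replicate 5, 3695 in effluent.

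**Figure D3:**
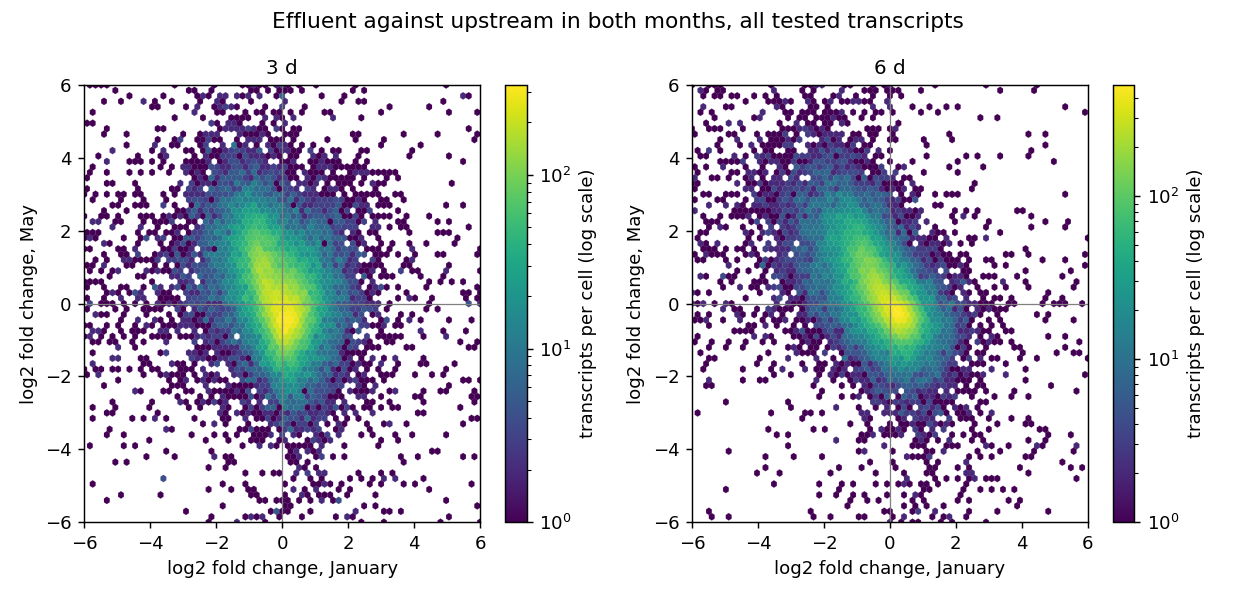
Log2 fold change of effluent against upstream in January (horizontal) and May (vertical) for each tested transcript at 3 d (left) and 6 d (right); colour gives transcripts per cell on a log scale, and points beyond 6 log2 units are outside the axes. Values slope downwards, with r of -0.22 at 3 d and -0.60 at 6 d.

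Along the first principal component, which held 41.9% of the variance at 3 d and 42.3% at 6 d, 3 d May effluent and downstream larvae lay at one end, and 3 d January effluent and downstream larvae lay at the other together with most May upstream larvae. The 3 d group means were -159 ± 22.9 (May effluent), -153 ± 27.3 (May downstream), -36.3 ± 18.8 (January upstream, n = 4), 106 ± 43.8 (January effluent), 127 ± 64.0 (January downstream) and 108 ± 87.5 (May upstream), as SD with n = 5 unless given. At 6 d the May effluent and downstream libraries lay between -169.7 and -134.2, and the lowest library was January upstream replicate 1 at -170.2, while the other January upstream libraries lay between -25.4 and 19.02.

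**Figure D4:**
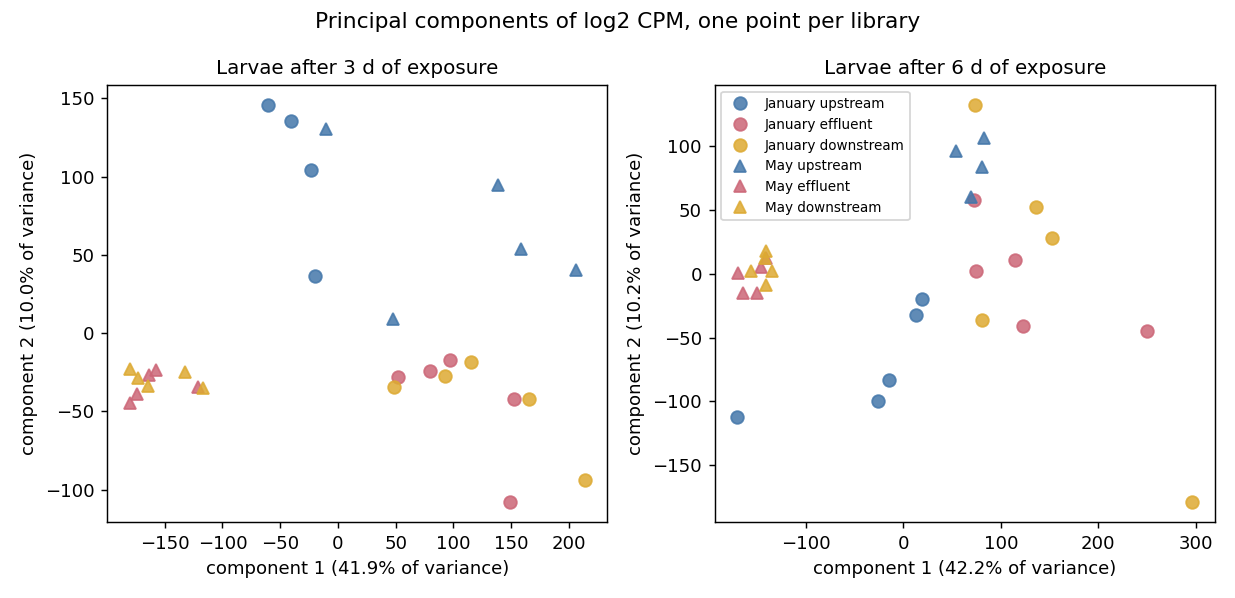
First and second principal components of log2 CPM for the libraries of 3 d (left) and 6 d larvae (right), coloured by site with January as circles and May as triangles. May effluent and downstream libraries sit at the low end of component 1, at 6 d together with January upstream replicate 1, and the May upstream mean at 3 d is 108.

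A small set of transcripts moved the same way in both months, at both ages and at both sites. It held 20 transcripts that were higher than upstream in all 8 comparisons and 5 that were lower, of 37511 tested in all 8, where independence of the months would give 404 and 154. ENSDART00000128008.3 (931 bases) rose in May 6 d effluent from 5.42 ± 1.46 CPM upstream (n = 4) to 22.1 ± 2.89 (n = 5), a log2 fold change of 2.02 ± 0.51 (SE; edgeR adjusted p = 0.00341), and in January 3 d effluent by 2.82 ± 0.67 (edgeR adjusted p = 0.00408; 1.75 and 0.105 with the replicate axis, and adjusted p of 0.000101 to 0.105 over the alternatives). Without January 3 d upstream replicate 4 that January 3 d effluent rise was 3.71. Its January 3 d downstream rise of 2.94 ± 0.68 did not pass with the replicate axis (1.695, edgeR adjusted p = 0.149, range over the alternatives 2.39e-05 to 0.149). In January 6 d downstream water its rise of 1.59 ± 0.46 did not pass without downstream replicate 5 (0.67, edgeR adjusted p = 0.151) nor in 5 other alternatives (0.41 to 1.55), with adjusted p from 0.0025 to 0.409 over the alternatives. Its rise in January 6 d effluent (1.38 ± 0.46, edgeR adjusted p = 0.0284) did not pass in 8 of 21 alternatives, with adjusted p from 0.00314 to 0.136. It was then 1.15 to 1.34 in the 5 that left out upstream replicate 1, 2 or 3 or effluent replicate 3 or 5, 1.38 in a fit of January alone, 0.91 without the libraries of low TMM factor and 0.68 with the replicate axis. ENSDART00000149062.2 (2240 bases) rose in May 3 d effluent from 3.35 ± 2.06 to 11.3 ± 0.811 CPM (n = 5 each), a log2 fold change of 1.75 ± 0.29 (edgeR adjusted p = 2.11e-05). Its rise in May 6 d effluent was smaller, 0.84 ± 0.31 (edgeR adjusted p = 0.0355), and in 7 of the 9 fits that left out a library it was 0.74 to 0.84 and did not pass. With the replicate axis it was 0.42 (edgeR adjusted p = 0.207, range over the alternatives 1.82e-05 to 0.207). It also did not pass with no filter on low counts (0.82, edgeR adjusted p = 0.0547) or with the replicate block (0.84, 0.0591). In a fit of January alone its January 6 d rises of 1.16 in effluent and 1.035 downstream did not pass (edgeR adjusted p = 0.0684 and 0.0887). ENSDART00000156406.3 (837 bases) fell in May 3 d effluent from 19.1 ± 13.3 to 3.08 ± 0.335 CPM (n = 5 each; log2 fold change -2.63 ± 0.51, edgeR adjusted p = 0.000138). With the replicate axis its January 3 d falls of -2.10 and -1.99 did not pass in effluent (-1.16, edgeR adjusted p = 0.261, range over the alternatives 6.53e-05 to 0.261) and downstream (-1.02, 0.39, range 8.34e-05 to 0.39). In January 6 d effluent its fall of -1.44 did not pass in 3 of 21 alternatives, in a fit of January alone (-1.44, edgeR adjusted p = 0.115), with the replicate axis (-0.66, 0.0991) and without effluent replicate 5 (-1.25, 0.051), with a range of 0.00134 to 0.115. Downstream its fall of -1.46 did not pass in a fit of January alone (-1.47, edgeR adjusted p = 0.0986, range 0.00208 to 0.0986). ENSDART00000148948.2 (662 bases) fell from 15.3 ± 6.55 to 3.58 ± 0.939 CPM in the same comparison (log2 fold change -2.09 ± 0.34, edgeR adjusted p = 1.6e-05). Its fall in January 6 d effluent of -1.04 (edgeR adjusted p = 0.00848) became -0.42 without the libraries of low TMM factor (0.26, range 0.00109 to 0.26). With the replicate axis its January 3 d falls of -1.25 and -1.48 did not pass in effluent (-0.98, edgeR adjusted p = 0.202, range 0.000151 to 0.202) and downstream (-1.23, 0.102, range 0.0002 to 0.102). The number called in all 8 was 9 without May 6 d upstream replicate 2, 12 without replicate 1 or replicate 4 of that group, and 10 to 75 under the other settings.

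Larvae in upstream water changed in many transcripts from 3 to 6 d. In January upstream larvae 5820 of 34491 transcripts were higher at 6 d and 5071 lower, and in May 3702 of 32367 were higher and 5146 lower. Of these changes, 2255 transcripts rose and 3034 fell in both, against 628 and 814 for independent lists, and 90 went opposite ways, with r of 0.66 across 31429 transcripts. Whether the change with age differed between months was not tested. With fragment length as a covariate the May count of 8848 calls became 5224.

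In May, transcripts that rise from 3 to 6 d in upstream larvae were more often called higher than lower in effluent and downstream larvae, and those that fall more often lower than higher. At 3 d in effluent, 35.7% of the 5706 transcripts that rise with age in January upstream larvae were higher and 20.5% lower. Of the 5071 that fall with age, 49.1% were lower and 13.5% higher. Of transcripts in neither class, 27.0% were higher and 26.5% lower. In January the rising and the falling class were both more often higher than lower at both sites and ages. This was not particular to them, since transcripts in neither class were also more often higher than lower. Their shares were 13.8% and 8.01% (3 d effluent), 16.5% and 11.8% (3 d downstream), 14.9% and 12.8% (6 d effluent), and 16.05% and 15.15% (6 d downstream). At 3 d, of the 3654 that rise with age in May upstream larvae, 24.9% were higher and 5.56% lower in effluent and 29.7% and 4.598% downstream. Of the 5146 that fall, 18.15% and 7.42% were higher and lower in effluent and 19.4% and 11.8% downstream. The stage index was -2.05 ± 0.43 in effluent and -2.004 ± 0.20 downstream against -4.39 ± 0.21 upstream at 3 d (SD, n = 5 each), and 3.69 ± 0.15 and 3.36 ± 0.35 (n = 5 each) against 0.83 ± 0.25 (n = 4) at 6 d. Each effluent and downstream library in May lay above each upstream library of its age. These 4 differences of 2.35, 2.39, 2.87 and 2.54 log2 units passed the exact permutation test (two-sided p = 0.00794 each, the smallest possible; adjusted p = 0.0159). In the 5 of 9 cases that left out an effluent or downstream library, the May 6 d differences stayed at 2.82 to 2.91 and 2.44 to 2.67 log2 units, and could not pass, since the smallest p of the exact permutation test was then 0.0286 and the adjusted p 0.0508 (range 0.0159 to 0.0508 over the alternatives). In January the differences did not pass. They were -0.04 in effluent and 0.30 downstream at 3 d (exact permutation test, adjusted p = 0.889 and 0.354), and -0.69 and -0.69 at 6 d (adjusted p = 0.0508 and 0.106). Without upstream replicate 3 or without effluent replicate 2 the January 6 d effluent difference passed (adjusted p = 0.0254 and 0.0381), as did the downstream difference without downstream replicate 3 (adjusted p = 0.0381); over the alternatives the adjusted p ranged from 0.0254 to 0.417 in effluent and from 0.0381 to 0.417 downstream. Whether the index difference itself changed with month was not tested, since the index is built from different transcripts in each.

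**Figure D5:**
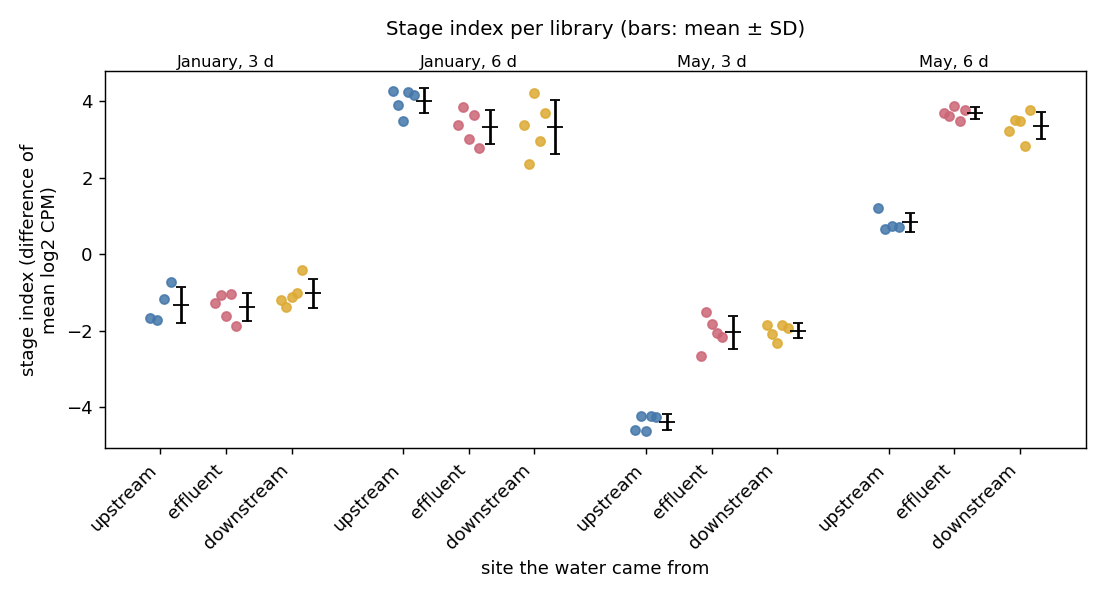
Stage index per library (mean log2 CPM of transcripts that rise from 3 to 6 d less that of those that fall), by site, month and age, with the mean ± SD; the index is built from different transcripts in January and May. May effluent and downstream libraries lie above the upstream libraries of their age, with means 2.35 to 2.87 log2 units higher.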

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

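The tests on depth, fragment length, abundance, the replicate axis and developmental stage were chosen only after the difference between months had been seen, and the bounds for developmental stage and for the calls kept with a covariate only after their values were known. The site difference differed between May and January for 19994 transcripts in effluent and 20925 downstream at 3 d, and for 19253 and 19001 at 6 d.

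The pattern is that January and May fold changes went mostly opposite ways, with r of -0.22 to -0.60 over both sites and ages. The tables argue against depth (r of -0.25 to -0.63 with every library thinned to 20000000 reads), rare transcripts (r of -0.42 to -0.68 at a mean log2 CPM of 5 or more) and developmental stage (largest absolute r of 0.257 between site fold changes and the change with age of the other month) as the whole cause. As a covariate, fragment length left r at -0.17 (3 d effluent) and at -0.27 to -0.62 (the other cases). It left 18988 to 21968 calls of the May minus January difference, which argues against it as the whole cause. At 6 d the replicate axis left r at -0.46 and -0.42 and 16356 to 16372 calls, which argues against that axis alone as the whole cause there. Differences between replicates along other directions were not tested and stay open. Taken from a single month, the axis held 32.2% (January) and 12.8% (May) of the variance within groups at 6 d. It correlated with fold changes of the other month at absolute r of 0.0736 (May axis) to 0.279 (January axis). The r of -0.17 and the highest of these at 6 d missed the bounds fixed before their values were known. Both verdicts therefore rest on the later bound on calls kept, and a partial role of either stays open. At 3 d the replicate axis stays open as the whole cause too. There it correlated with the fold changes of the other month at absolute r of 0.277 to 0.470. As a covariate it gave r of 0.01 in effluent and -0.06 downstream at 3 d. Part of the 3 d pattern may therefore lie along a direction in which dishes of a group also vary. That correction also takes out any effect of the water along the axis. A seasonal difference in the water is an untested biological explanation. Exposure run, library quality and a separate sequencing of the May upstream libraries cannot be told apart from it.

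In fits of the libraries compared alone, the splits argue against chance assignment of libraries for the comparisons with upstream. In each, 1 of 41 splits, the real one, gave as many calls, the smallest share that 41 splits allow. The real and highest other counts were 6673 and 3 (effluent January 3 d), 17598 and 0 (effluent May 3 d), 8671 and 2 (downstream January 3 d), 16790 and 1 (downstream May 3 d), 5778 and 1 (effluent January 6 d), 20671 and 8183 (effluent May 6 d), 1526 and 1 (downstream January 6 d) and 20893 and 6615 (downstream May 6 d). For downstream against effluent in January 3 d, May 3 d and January 6 d edgeR gave a real count of 0, so that all 41 splits had to give at least as many and decide nothing, with highest other counts of 1, 2 and 2; the report gives the counts at an unadjusted p under 0.05 and by DESeq2 and limma. For May 6 d a fit of those 10 libraries gave 12 calls against 3 in the highest other split, while the fit of all 6 d libraries gave 0. For the May minus January differences 1 of 25 splits, the real one, gave as many calls. The real and highest other counts were 18510 and 6 (3 d effluent), 19557 and 4630 (3 d downstream), 20853 and 11417 (6 d effluent) and 17265 and 0 (6 d downstream). These splits exchanged sites within each month, so they test for no site difference in either month. They cannot decide whether an equal site difference in both months would give such counts. The splits also argue against chance assignment for 6 d against 3 d larvae, with 10891 and 3180 in January and 8848 and 2 in May, each with 1 of 41 splits.

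In 12 of 96 tests of a measure in a group, a library stood apart from the others of its group, where chance gives about 1 in 20, or 4.8. January 6 d upstream replicate 1 had 33217 detected transcripts, against 30322 in the next library. January 6 d downstream replicate 5 had 23013 detected transcripts, against 28215 in the next, and 54.6 CPM of ENSDART00000128008.3, against 17.2; its TMM factor of 0.557 (next 0.913) and mean fragment length of 135 bases (next 153.2) were the lowest of its group and of all 29 libraries of 6 d. January 3 d downstream replicate 3 had a TMM factor of 0.851 and a mean fragment length of 149.7 bases, the lowest of its group in both. May 6 d downstream replicate 2 had a mean fragment length of 180 bases, the highest of its group. May 6 d upstream replicate 1 had a stage index of 1.21, the highest of its group. For ENSDART00000128008.3, January 3 d effluent replicate 4 was high at 15.7 CPM, and May 3 d downstream replicate 2 and May 6 d effluent replicate 1 were low at 3.67 and 17.1 CPM. January 3 d upstream replicate 4 was high at 5.49 CPM of ENSDART00000149062.2, and May 3 d downstream replicate 2 low at 1.181 CPM of ENSDART00000156406.3.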

How the results depend on the processing

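The replicate axis, fragment length, thinning, quality weights, TMM limit and fits of the groups compared alone were chosen after seeing the data, as was every alternative for overlaps, detected transcripts and the age comparison. Median-of-ratios factors, no filter on low counts, the length offset, thinning and leaving out libraries of low TMM factor kept all 18 counts of calls within 1.5 times. The cause of the changes below was not tested. The planned tests of gene lists, with their estimated correlation between genes, were not run, and the length offset was made per transcript. Fitting a month alone gave 3533 and 4417 calls in January 6 d effluent and downstream, and 22465 and 21802 in May 6 d; the shared effluent and downstream calls were then 2881 in January and 19898 in May, the January and May calls of the same direction 85 in effluent, and those of opposite direction 2635 in effluent and 3230 downstream. Fits of the groups compared alone gave 5778 and 1526 calls in January 6 d effluent and downstream, 20893 in May 6 d downstream and 12 for downstream against effluent in May 6 d. The replicate axis gave 2230 and 1489 calls (January 3 d effluent and downstream), 10839 and 10763 (May 3 d), 1925 and 2056 for the 3 d May minus January differences, and 1 and 2 for downstream against effluent in January at 3 d and 6 d. Shared effluent and downstream calls were then 1164 and 9551 (3 d January and May), January and May calls of the same direction 638 and 328 (3 d effluent and downstream) and 295 and 313 (6 d), and 3 d opposite calls 186 and 150. Fragment length gave 6683 calls in January 3 d downstream, 5224 between ages in May, 460 calls of the same and 3388 of opposite direction in both months (3 d downstream), and 9228 opposite in 6 d effluent. Quality weights gave 21866 and 21715 calls in May 6 d effluent and downstream, 1 and 103 for downstream against effluent at 6 d in January and May, 10579 and 19423 shared calls (January 3 d and May 6 d), 6024 opposite calls in 3 d effluent, and 1709, 495 and 456 calls of the same direction in both months (3 d downstream, 6 d effluent, 6 d downstream). DESeq2 gave 76, 76, 107 and 56 for downstream against effluent (January 3 d, May 3 d, January 6 d, May 6 d), and 283 and 311 calls of the same direction in both months (6 d effluent and downstream). The transcripts called in all 8 comparisons numbered 10 with no filter, 49 with DESeq2, 16 with the replicate block, 75 with quality weights and 15 with the replicate axis.

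Replicate numbers did not pair all libraries of any comparison. In none did every pair of the same number correlate above 0.1 in its deviations, nor did each library correlate best with its own number. Downstream against effluent in January 6 d came nearest, with 3 of 5 pairs above 0.1. Its mean r was 0.195 for the same number and -0.043 for other numbers, so a part shared by some libraries of a number stays open there. The replicate block gave 1 call for downstream against effluent in January 6 d and moved no other count of calls of a single comparison by over 1.5 times; January 3 d effluent had 6960 and May 3 d effluent 19613, and the call of ENSDART00000149062.2 in May 6 d effluent was lost (edgeR adjusted p = 0.0591).

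Leaving out each library in turn gave 4907 to 9224 calls in January 3 d effluent, 6746 to 12465 in January 3 d downstream, 6330 to 11111 in January 6 d effluent and 7666 to 13581 in January 6 d downstream. For downstream against effluent it gave 0 to 1 (January 3 d), 0 to 2 (May 3 d), 0 to 9 (January 6 d) and 0 to 2 (May 6 d). Shared effluent and downstream calls ranged from 4002 to 7212 (January 3 d) and from 5129 to 9204 (January 6 d). January and May calls of the same direction ranged from 662 to 1434 and from 597 to 1195 (3 d effluent and downstream), and from 90 to 177 and from 104 to 194 (6 d). Opposite calls ranged from 2009 to 4208 and from 3305 to 6408 (3 d effluent and downstream), and from 3309 to 5800 and from 3709 to 6460 (6 d). Those called in all 8 ranged from 9 to 31. In the January comparisons of effluent and downstream with upstream, the lowest counts came without upstream replicate 2 at 3 d and without upstream replicate 1 at 6 d.

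The stage index in January 3 d effluent changed sign with 500 transcripts per direction, to 0.0437, and ranged from -0.18 to 0.15 with a library left out, passing in none. It ranged from -0.82 to -0.55 in January 6 d effluent and from -0.91 to -0.45 in January 6 d downstream. In May 6 d it ranged from 2.81 to 2.99 in effluent and from 2.44 to 2.67 downstream; 5 of 9 cases of each gave an adjusted p of 0.0508 over 8 comparisons, with an exact p of 0.0286, the smallest that 4 libraries against 4 allow. The detected transcripts of the January 6 d comparisons and of January 3 d effluent lost their call as given in the report. Of 352 values of the 4 named transcripts under other settings 23 lost the call and 0 changed sign, 10 of them with the replicate axis and 6 in a fit of a month alone.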

Other observations

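In May upstream larvae, 32.4% of the 2715 transcripts above a log2 CPM of 6 were lower at 6 d than at 3 d and 12.6% higher, whereas in January 27.2% of 2172 were lower and 34.02% higher. This difference between months was not tested. Site fold changes at 3 d and 6 d had much in common within a month: in May effluent 5604 transcripts were higher and 5358 lower at both ages, with 96 opposite, and in January effluent 3634 and 1717, with 7 opposite. These ages share no library.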
